A study of Homo sapiens with 16 samples.

How the data were processed

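RNA sequencing of total RNA was read for 16 libraries of human melanoma cell lines that had become resistant to drugs against the MAPK pathway. The cells were the resistant derivatives DR A375 and 451Lu BR, given as A375 and 451Lu. A375 cells had been kept on dabrafenib (0.5 µM) and trametinib (0.05 µM), and 451Lu cells on dabrafenib (1 µM). Dabrafenib inhibits BRAF and trametinib inhibits MEK. Drug was then replaced with DMSO for 6, 24 or 48 h in A375 and for 24, 72 or 120 h in 451Lu, with 2 libraries per group and 4 groups per line. The labels describe the 451Lu cells in 2 ways: the treatment notes name dabrafenib alone, while the source name says resistant to dabrafenib and trametinib. The dose used here is the one in the treatment notes.

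Per the submitters' processing notes, the authors aligned reads with TopHat2 2.1.0 and Bowtie 1.0.0 to the human genome build GRCh38. The deposited table holds raw read counts per Ensembl gene. The read counter, the annotation release, the strand setting and any filter on genes are not given in the sources used here. The table has 30813 genes, each with at least 1 count in total. It has 1 column of counts for each of the 16 libraries. Library totals ran from 9714190 to 16691725 counts. Because the strand setting is not given, counts of genes that overlap on opposite strands may be shared between them. Reads of near-identical genes may also be divided in a way that cannot be read from the table.

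Each line was fitted on its own with edgeR 4.0.16 in R 4.3.3, as 1 factor with 4 groups. The fit used TMM scaling, filterByExpr (minimum count 10, minimum total 15), a quasi-likelihood negative binomial model and the quasi-likelihood F test, which leaves 4 residual degrees of freedom per line. The dispersion estimates are moderated across genes, so the p-values rest on more degrees of freedom than these 4. There were 14449 genes tested in A375 and 13851 in 451Lu. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. The difference between the lines in the 24 h change came from a joint fit of all 16 libraries over 15481 genes with 8 residual degrees of freedom. Line and drug cannot be separated in that contrast, since each line came off its own treatment. Overlap between the lines was tested with Fisher's exact test, one-sided, over 12814 genes tested in both. The lines share no on-drug libraries. Times within a line do share them, so no overlap was computed between comparisons of 1 line.

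Levels are CPM, counts scaled by TMM-adjusted library sizes, as mean ± SD with n = 2. TMM scaling assumes that most genes do not change, or that rises and falls balance. In 451Lu at 120 h 73.8% of genes tested were called. Levels, small changes and the numbers of genes higher and lower are therefore relative to the other genes, not amounts of RNA per cell. Log2 fold changes are the fitted values ± SE. The SE is the absolute log2 fold change divided by the square root of its F statistic, not the standard error of the fitted coefficient. The SE of a difference between the lines therefore need not follow from the SEs of the 2 lines. Where a group had 0 counts in both libraries, the fold is a lower bound against a floor of 3 counts summed over the group's 2 libraries. Where it had 1 to 3 counts, a ratio is given with a 95% counting interval (exact Clopper-Pearson). Intervals and floors cover counting error only. The common biological coefficient of variation was 3.19% in A375 and 4.98% in 451Lu. The ratio of chi-square to degrees of freedom between the 2 libraries of a group ran from 1.29 in A375 at 6 h to 6.03 in 451Lu at 120 h. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

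The tests, the 19 gene lists, the rule for named genes and the alternatives were set before the data were examined. The lists were ERK pathway output, AP-1 factors, immediate-early genes, melanocyte differentiation, mesenchymal and invasive genes, DNA replication and S phase, G2 and mitosis, cell cycle inhibitors and p53 targets, apoptosis regulators, inflammatory cytokines and NF-kB targets, interferon response, integrated and ER stress response, cholesterol synthesis, glycolysis, ribosome biogenesis, receptor tyrosine kinases, heat shock, mitochondrially encoded genes, and markers of other cell types. Of 397 list entries, 393 matched a gene of the table by symbol. Some genes stand in more than 1 list: LIF and IL11 belong to both ERK pathway output and the cytokine list, and MCL1 and BCL2A1 also count as apoptosis regulators. Each list was tested against all other genes with camera (limma 3.58.1, preset inter-gene correlation 0.01), with adjustment over the 19 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Counts of list members past the test are given over all genes and adjusted over the list alone.

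Named genes followed a fixed rule. For each time off drug it took the 6 largest rises and the 6 largest falls among genes past the threshold with an average log2 CPM of at least 2 and with both libraries of 1 group above both of the other. It then took up to 3 members of each list with the smallest p. DUSP6, SPRY4, FOSL1, JUNB, MITF, AXL, CCND1 and MAPK3 were named at every time whatever their p. Some genes that the rule takes are not reported here. For successive times and for the line difference it took the 5 largest changes each way. Genes outside the rule are said to have been chosen after their values were seen.

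Alternatives were DESeq2 1.42.0, its median-of-ratios size factors in edgeR, no filter, a filter of CPM 1 in 2 libraries, the replicate number as a block, a test against a fold change of 1.5, fits of the compared groups alone or of all 16 libraries, and each compared library left out in turn. The labels do not say whether replicate numbers pair libraries across groups. Correlations of the replicate differences were 0.133, 0.137 and 0.136 between the 3 off-drug groups of 451Lu. With the on-drug group of 451Lu they ran from -0.0195 to 0.00977, and in A375 from -0.0393 to 0.0232. The block was used as an alternative.

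The scripts were tested on simulated data with changes added to genes of known identity. For each fold change 50 genes of a line were changed at 24 h, as many up as down, and all others were left unchanged. In the real A375 data 10486 of 14449 genes changed at 24 h. The recovered and false shares therefore belong to a setting with few changes and were not tested at the real extent of change. With edgeR on simulated A375 data, 58%, 74%, 92% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 13 unchanged genes were called, 7.43% of all calls. On simulated 451Lu data the recovered shares were 40%, 68%, 88% and 98%, with 2 unchanged genes called, 1.34% of calls. For the line difference they were 26%, 52%, 76% and 90%, with 7 unchanged genes called. DESeq2 recovered 38%, 64%, 86% and 94% on simulated A375 data and 26%, 56%, 80% and 94% on simulated 451Lu data. Camera gave an unadjusted p below 0.05 for 0 of 200 random lists in each line. The genes of those lists were simulated independently of each other. This count therefore cannot show how camera treats lists of correlated genes. No splits of the samples were counted, since 2 libraries against 2 are too few, and no library was left out of the main values.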

Results

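Gene expression was measured by RNA sequencing in A375 and 451Lu, human melanoma cell lines that carry activated BRAF and had become resistant to inhibitors of the MAPK pathway. The cells were the resistant derivatives DR A375 and 451Lu BR, called A375 and 451Lu from here on. There were 8 libraries per line: 2 from cells kept on drug and 2 at each of 3 times after the drug was withdrawn. A375 was sampled at 6, 24 and 48 h and 451Lu at 24, 72 and 120 h. There was no separate on-drug group for each time, so time in culture cannot be told apart from withdrawal. Total counts per library ran from 10863255 to 16691725 in A375 and from 9714190 to 16447548 in 451Lu. Genes encoded by the mitochondrial genome took 5.53% and 4.81% of counts in A375 on drug and 2.60% to 3.70% off drug. In 451Lu they took 6.11% and 5.51% on drug and 3.97% to 5.08% off drug. FN1, which encodes the matrix protein fibronectin, took 0.0671% and 0.0741% of counts in 451Lu on drug and 6.15% and 6.25% at 120 h. Levels are given as CPM (counts scaled by library size, mean ± SD, n = 2) and changes as log2 fold changes ± SE, each off drug against on drug unless said otherwise.

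The first comparison asked how expression in A375 had changed 6 h after both drugs were withdrawn. LIF (ENSG00000128342, chromosome 22, 30240447 to 30246851), a cytokine of the interleukin 6 family, rose from 4.78 ± 0.255 to 3493 ± 57.1 CPM (SD, n = 2), a log2 fold change of 9.51 ± 0.07 (SE) with adjusted p = 5.36e-43. IL11 (ENSG00000095752, chromosome 19, 55364389 to 55370463), another cytokine of that family, had no counts on drug and 124 ± 6.36 CPM at 6 h, at least 1300-fold higher. The neuronal activity gene ARC was at least 364-fold higher, IGFN1 at least 155-fold and BRINP2 at least 68.4-fold, each with 0 counts on drug. SLC12A8, which encodes a membrane transporter, had 1 count on drug and a ratio of 2577 (counting interval 462 to 101800). BMF, which encodes a BH3-only protein that promotes cell death, fell from 21.5 ± 2.51 CPM to 2 counts in all, a ratio of 238 (counting interval 65.7 to 1971). P2RX7, which encodes an ATP-gated channel, fell 20.04-fold from 199.8 ± 3.80 to 9.93 ± 1.68 CPM.

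ERK signalling genes rose at 6 h in A375. DUSP6 (ENSG00000139318, chromosome 12, 89347232 to 89353271), a phosphatase that switches ERK off, rose from 29.7 ± 0.739 to 334 ± 0.460 CPM, a log2 fold change of 3.49 ± 0.06 with adjusted p = 4.93e-33. SPRY4, an inhibitor of receptor signalling, rose 6.89-fold, and CCND1, which encodes cyclin D1, rose 12.2-fold from 31.5 ± 2.26 to 386 ± 3.92 CPM. EMP1 rose 59.2-fold and IER3 37.3-fold. In all, 17 of the 22 genes of ERK pathway output rose and 3 fell (18 and 3 adjusted over the list alone), with a median log2 change of 1.77, camera adjusted p = 4.43e-40 and adjusted p = 0.00947 with an estimated correlation. MAPK3, which encodes the kinase ERK1, fell with a log2 fold change of -0.57 ± 0.07.

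At 6 h in A375, FOSL1 (ENSG00000175592, chromosome 11, 65892049 to 65900573), which encodes the AP-1 factor FRA1, rose 15.5-fold from 11.9 ± 0.901 to 183 ± 9.55 CPM, and JUNB rose 3.15-fold, while the stress-responsive ATF3 fell 6.38-fold. The 9 AP-1 factors split into 7 that rose and 2 that fell, the same counts adjusted over the list alone, with camera adjusted p = 0.0631, not past the threshold. EGR1 rose 60.5-fold, EGR3 25.2-fold and MCL1, which encodes a survival protein of the BCL2 family, 5.44-fold. Among 20 immediate-early genes 18 rose and 1 fell, with the same counts adjusted over the list alone, a median log2 change of 1.68, camera adjusted p = 3.76e-12 and adjusted p = 0.0295 with an estimated correlation.

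Genes of melanocyte identity fell at 6 h in A375, led by MITF (ENSG00000187098, chromosome 3, 69739435 to 69968337), the master regulator of the lineage, which went from 410.0 ± 6.73 to 59.8 ± 5.70 CPM, a log2 fold change of -2.78 ± 0.06 with adjusted p = 5.77e-30. Of 20 melanocyte genes tested, 17 fell and 3 rose (also adjusted over the list alone). The list had camera adjusted p = 2.00e-04 and adjusted p = 0.0962 with an estimated correlation. Of the list's members, BCL2A1, a survival gene of the BCL2 family, rose 5.64-fold. Among 28 mesenchymal and invasive genes 20 rose and 3 fell (the same counts adjusted over the list alone). For this list camera gave adjusted p = 1.03e-08, and adjusted p = 0.0412 with an estimated correlation. Examples were the integrin gene ITGA3 at 9.67-fold, the matrix gene THBS1 at 16.4-fold and NT5E, which encodes the surface enzyme CD73, at 11.6-fold. AXL (ENSG00000167601, chromosome 19, 41219203 to 41261766), a receptor tyrosine kinase of the invasive melanoma state, went from 0.368 ± 0.353 to 2.69 ± 0.150 CPM, a log2 fold change of 2.91 ± 0.41. That AXL change was 2.105 without on-drug replicate 1 and 4.40 without on-drug replicate 2. Of 7 markers of other cell types tested, KRT18 rose 2.75-fold, and 4 fell, among them LUM, to 14.8 ± 1.14 CPM (1 and 4 adjusted over the list alone, camera adjusted p = 0.715).

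Growth-related groups moved apart at 6 h in A375. All 21 ribosome biogenesis genes rose, also adjusted over the list alone, with a median log2 change of 1.28, camera adjusted p = 4.44e-19 and adjusted p = 0.010002 with an estimated correlation. RRP12 rose 3.81-fold and DKC1 2.66-fold. In contrast, 23 of 26 G2 and mitosis genes fell and 0 rose (also adjusted over the list alone), with a median log2 change of -0.85, camera adjusted p = 3.18e-11 and adjusted p = 0.0180 with an estimated correlation. CENPF, a kinetochore gene, fell 4.20-fold, KIF20A, a mitotic kinesin gene, 4.61-fold, and TOP2A, which encodes the DNA topoisomerase of dividing cells, 2.43-fold. S phase genes went both ways: 18 of 27 fell, such as MCM2 at 2.48-fold, and 7 rose, such as RRM2 at 2.08-fold (the same counts adjusted over the list alone). Camera gave adjusted p = 0.0139 for the list, and adjusted p = 0.399 with an estimated correlation. Heat shock genes rose in 9 of 12 cases and fell in 1 (the same adjusted over the list alone), with camera adjusted p = 2.00e-04 and adjusted p = 0.104 with an estimated correlation, and HSPA8 rose 3.11-fold. Among 20 glycolysis genes 16 rose and 3 fell (the same adjusted over the list alone), HK2 by 4.96-fold and PFKFB4 by 13.6-fold. The list had camera adjusted p = 2.12e-05 and adjusted p = 0.37 with an estimated correlation.

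Cytokine genes as a class rose at 6 h in A375: 14 of 17 inflammatory cytokines and NF-kB targets rose and 0 fell, also adjusted over the list alone. For this list camera gave adjusted p = 8.31e-18, and adjusted p = 0.0208 with an estimated correlation. CXCL8, a neutrophil attractant, rose 66.1-fold. Of 19 interferon response genes, 15 fell, such as STAT2 at 3.504-fold, and 2 rose (the same adjusted over the list alone). Camera gave adjusted p = 0.00959 for the list, and adjusted p = 0.0962 with an estimated correlation. In the list of apoptosis regulators 11 genes rose and 6 fell of 17, the same adjusted over the list alone. The list had camera adjusted p = 0.0134 and adjusted p = 0.0962 with an estimated correlation. The members with the smallest p were survival genes that rose (MCL1 and BCL2A1) and BMF, which fell. Of 23 cell cycle inhibitors and p53 targets, 8 rose, such as CDKN1A, which encodes the inhibitor p21, at 3.55-fold, and 13 fell, such as TP53INP1 at 16.6-fold (the same adjusted over the list alone, camera adjusted p = 0.377).

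Stress and lipid lists went both ways at 6 h in A375. Integrated and ER stress genes included a rise of HSPA5, an ER chaperone gene, of 2.84-fold and a fall of ATF4, which encodes the main factor of the integrated stress response, of 3.17-fold, with 9 up and 11 down of 20 (the same adjusted over the list alone, camera adjusted p = 0.326). Cholesterol synthesis had 6 up, INSIG1 by 12.6-fold, and 10 down, MVK by 5.67-fold, of 19 (6 and 11 adjusted over the list alone, camera adjusted p = 0.716). Among 15 receptor tyrosine kinases FGFR1 rose 4.69-fold and ERBB3 fell 7.35-fold, with 5 up and 7 down (the same adjusted over the list alone, camera adjusted p = 0.259). Of 13 mitochondrially encoded genes 11 fell and 1 rose (11 and 2 adjusted over the list alone, camera adjusted p = 0.0735), MT-CO1 by 1.52-fold. Across all genes, 10589 of 14449 changed, 5078 higher and 5511 lower, and 3462 of them by at least 2-fold. The balance turned with RLE size factors (5318 higher, 5198 lower) and with DESeq2 (4748 higher, 3853 lower). Against a fold change of 1.5, 4566 passed, and MAPK3, MT-CO1 and LUM, with adjusted p of 0.626, 0.392 and 0.571, did not. Over their 12 alternatives the lowest adjusted p were 1.89e-12, 7.05e-69 and 1.75e-07.

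**Figure D1:**
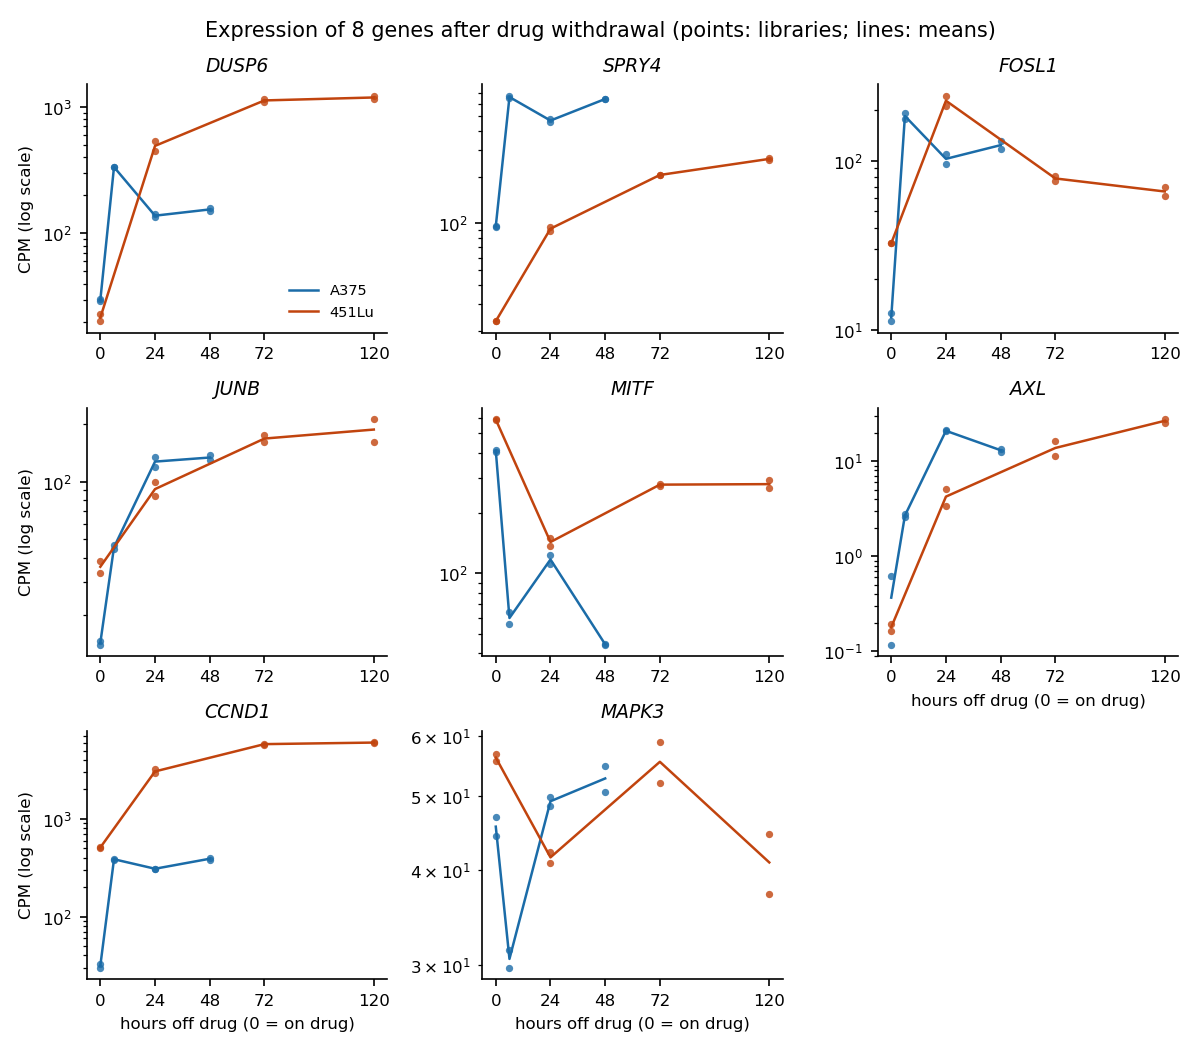
CPM on a log scale (vertical axes) against hours off drug (horizontal axes, 0 for cells on drug) for 8 genes, with points for the 2 libraries of a group and lines through their means. DUSP6 went from 29.7 to 334 CPM within 6 h in A375 and from 21.6 to 1184 CPM by 120 h in 451Lu, and MITF lay below its on-drug level at all 6 times.

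At 24 h off drug A375 cells were asked the same question. AREG, a ligand of the EGF receptor, rose from 0.187 ± 0.0699 to 737 ± 7.56 CPM, a log2 fold change of 11.85 ± 0.12 with adjusted p = 5.19e-40, and STC1, a secreted glycoprotein gene, rose from 0.265 ± 0.208 to 717 ± 17.0 CPM. For STC1 the log2 fold change of 11.41 was 10.74 without on-drug replicate 1 and 12.46 without on-drug replicate 2. IL11 was at least 3127-fold higher, ARC at least 404-fold, CD52 at least 142-fold and MYEOV at least 96.3-fold, from 0 counts on drug. GALNT3, which encodes an enzyme of O-linked glycosylation, fell 145-fold from 22.5 ± 0.617 CPM, and GYG2 fell 18.7-fold. Without 24 h replicate 1 the log2 fold change of GALNT3 was -7.87, against -7.18. DUSP6 was 4.63-fold higher, SPRY4 4.85-fold, CCND1 9.77-fold, FOSL1 8.70-fold and JUNB 8.86-fold. MITF was 3.51-fold lower, and AXL rose 58.2-fold to 20.9 ± 0.323 CPM. Its log2 fold change of 5.86 was 5.06 without on-drug replicate 1 and 7.35 without on-drug replicate 2. MAPK3 had a log2 fold change of 0.11 ± 0.07 with adjusted p = 0.117, not past the threshold.

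Of 22 genes of ERK pathway output, 17 rose and 4 fell at 24 h in A375 (the same adjusted over the list alone). For this list camera gave adjusted p = 4.61e-38, and adjusted p = 0.0187 with an estimated correlation. For the 20 immediate-early genes, 18 rose and 2 fell (the same adjusted over the list alone), with EGR1 at 122-fold and NR4A2, a nuclear receptor gene, at 47.5-fold, camera adjusted p = 5.06e-25 and adjusted p = 0.0187 with an estimated correlation. AP-1 factors had 6 up and 3 down of 9 (the same adjusted over the list alone), FOSB by 22.5-fold. Camera gave adjusted p = 0.00198 for the list, and adjusted p = 0.224 with an estimated correlation. Of the cytokine list, 16 of 17 rose and 0 fell, also adjusted over the list alone, CXCL8 by 302-fold (3.49 ± 0.0779 to 1058 ± 57.8 CPM). The list had camera adjusted p = 9.89e-30 and adjusted p = 0.0187 with an estimated correlation. Its median log2 change was 4.28, or 3.82 with genes at the floor set to their bound. Melanocyte genes fell in 15 of 20 cases and rose in 2 (the same adjusted over the list alone), DCT, a pigment enzyme gene, by 4.77-fold and MLANA, a melanosome antigen gene, by 3.85-fold. For this list camera gave adjusted p = 2.96e-12, and adjusted p = 0.0511 with an estimated correlation.

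Mesenchymal and invasive genes numbered 19 up and 7 down of 28 at 24 h in A375 (the same adjusted over the list alone), ITGA3 by 28.3-fold. Camera gave adjusted p = 5.43e-10 for the list, and adjusted p = 0.0511 with an estimated correlation. Cholesterol synthesis genes now rose in 15 of 19 cases and fell in 3 (the same adjusted over the list alone), INSIG1 by 21.2-fold. The list had camera adjusted p = 1.53e-07 and adjusted p = 0.224 with an estimated correlation. Glycolysis genes rose in 19 of 20 cases with 0 down, also adjusted over the list alone (camera adjusted p = 8.77e-11; adjusted p = 0.224 with an estimated correlation), and ribosome biogenesis genes in 16 of 21 with 1 down, also adjusted over the list alone (camera adjusted p = 0.00259; adjusted p = 0.133 with an estimated correlation). Heat shock genes had 8 up and 1 down of 12 (the same adjusted over the list alone, camera adjusted p = 0.0148, adjusted p = 0.224 with an estimated correlation). Of 26 G2 and mitosis genes 9 rose, PTTG1 by 2.32-fold, and 11 fell, FOXM1 by 1.99-fold (the same adjusted over the list alone, camera adjusted p = 0.572). Mitochondrially encoded genes had 9 of 13 down and 0 up, also adjusted over the list alone (camera adjusted p = 0.0237, adjusted p = 0.6 with an estimated correlation). Markers of other cell types had 3 up and 4 down of 7, also adjusted over the list alone, with LUM at 3.55-fold lower and camera adjusted p = 0.56. In all 10486 genes changed, 5234 higher and 5252 lower, and 4257 passed the test against 1.5-fold. More were higher than lower with RLE size factors (5405 and 5113) and with DESeq2 (4670 and 3763).

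By 48 h off drug, again against A375 on drug, DCT had fallen 32.1-fold from 3169 ± 70.0 to 98.7 ± 6.68 CPM, with adjusted p = 9.26e-39, MLANA 22.1-fold and MITF 9.28-fold. GALNT3 had 0 counts and was at least 165-fold lower, and ESRP1, a splicing regulator gene of epithelial cells, fell 68.4-fold. STC1 rose to 1426 ± 8.64 CPM and AREG to 1087 ± 23.6 CPM, while IL11 was at least 1199-fold, ARC at least 313-fold, MYEOV at least 224-fold and BRINP2 at least 165-fold higher. The log2 fold change of STC1, 12.40, was 11.73 without on-drug replicate 1 and 13.45 without on-drug replicate 2. LIF stood at 2195 ± 94.7 CPM and CXCL8 at 1617 ± 26.4 CPM, a log2 fold change of 8.85 ± 0.08. DUSP6 was 5.201-fold higher, SPRY4 6.69-fold, FOSL1 10.4-fold, JUNB 9.27-fold, CCND1 12.4-fold and AXL 36.5-fold. For AXL the log2 fold change of 5.19 was 4.39 without on-drug replicate 1 and 6.68 without on-drug replicate 2. MAPK3 had a log2 fold change of 0.21 ± 0.07 with adjusted p = 0.00556. That MAPK3 call ended in 3 of 12 alternatives, over which adjusted p ran from 0.00161 to 1: the test against 1.5-fold, without on-drug replicate 1 (log2 fold change 0.17) and without 48 h replicate 2 (0.15).

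Melanocyte genes fell in 17 of 20 cases at 48 h in A375 and rose in 3 (the same adjusted over the list alone), with a median log2 change of -2.12, camera adjusted p = 2.46e-25 and adjusted p = 0.00582 with an estimated correlation. All 17 genes of the cytokine list rose, also adjusted over the list alone, with camera adjusted p = 5.01e-28 and adjusted p = 0.0103 with an estimated correlation; the median log2 change was 4.18, or 3.85 with genes at the floor set to their bound. ERK pathway output had 17 up and 4 down of 22, also adjusted over the list alone, DUSP5 by 49.7-fold. For this list camera gave adjusted p = 4.50e-34, and adjusted p = 0.00582 with an estimated correlation. Immediate-early genes had 17 up and 2 down of 20, and mesenchymal and invasive genes 19 up and 6 down of 28, each the same adjusted over the list alone, with adjusted p of 0.0121 and 0.0154 with an estimated correlation. NT5E rose 28.4-fold and TGFBI, a matrix protein gene, 25.2-fold. G2 and mitosis genes had 15 up, UBE2C by 2.23-fold, and 7 down of 26 (the same adjusted over the list alone, camera adjusted p = 0.196). DNA replication genes had 7 up and 16 down of 27 (the same adjusted over the list alone). Camera gave adjusted p = 0.0278 for the list, and adjusted p = 0.41 with an estimated correlation.

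All 13 mitochondrially encoded genes fell at 48 h in A375, also adjusted over the list alone, MT-CO1 by 2.08-fold, with camera adjusted p = 1.47e-04 and adjusted p = 0.338 with an estimated correlation. Cholesterol synthesis had 14 up and 3 down of 19, also adjusted over the list alone (camera adjusted p = 7.74e-05, adjusted p = 0.26 with an estimated correlation). Interferon genes had 2 up, IRF7 by 10.3-fold, and 11 down of 19, MX2 by 3.02-fold (the same adjusted over the list alone, camera adjusted p = 0.102). Cell cycle inhibitors had 10 up and 12 down of 23 (the same adjusted over the list alone, camera adjusted p = 0.384), with CDKN1A at 2.76-fold higher, and the sign of their median log2 change, -0.21, differed from that of their mean, 0.50. Markers of other cell types had LUM at 8.20-fold lower, with 3 up and 4 down of 7 (the same adjusted over the list alone, camera adjusted p = 0.625). There were 10493 genes changed, 5287 higher and 5206 lower, and 4525 past the test against 1.5-fold. Without the low-count filter 5154 were higher and 5567 lower.

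**Figure D2:**
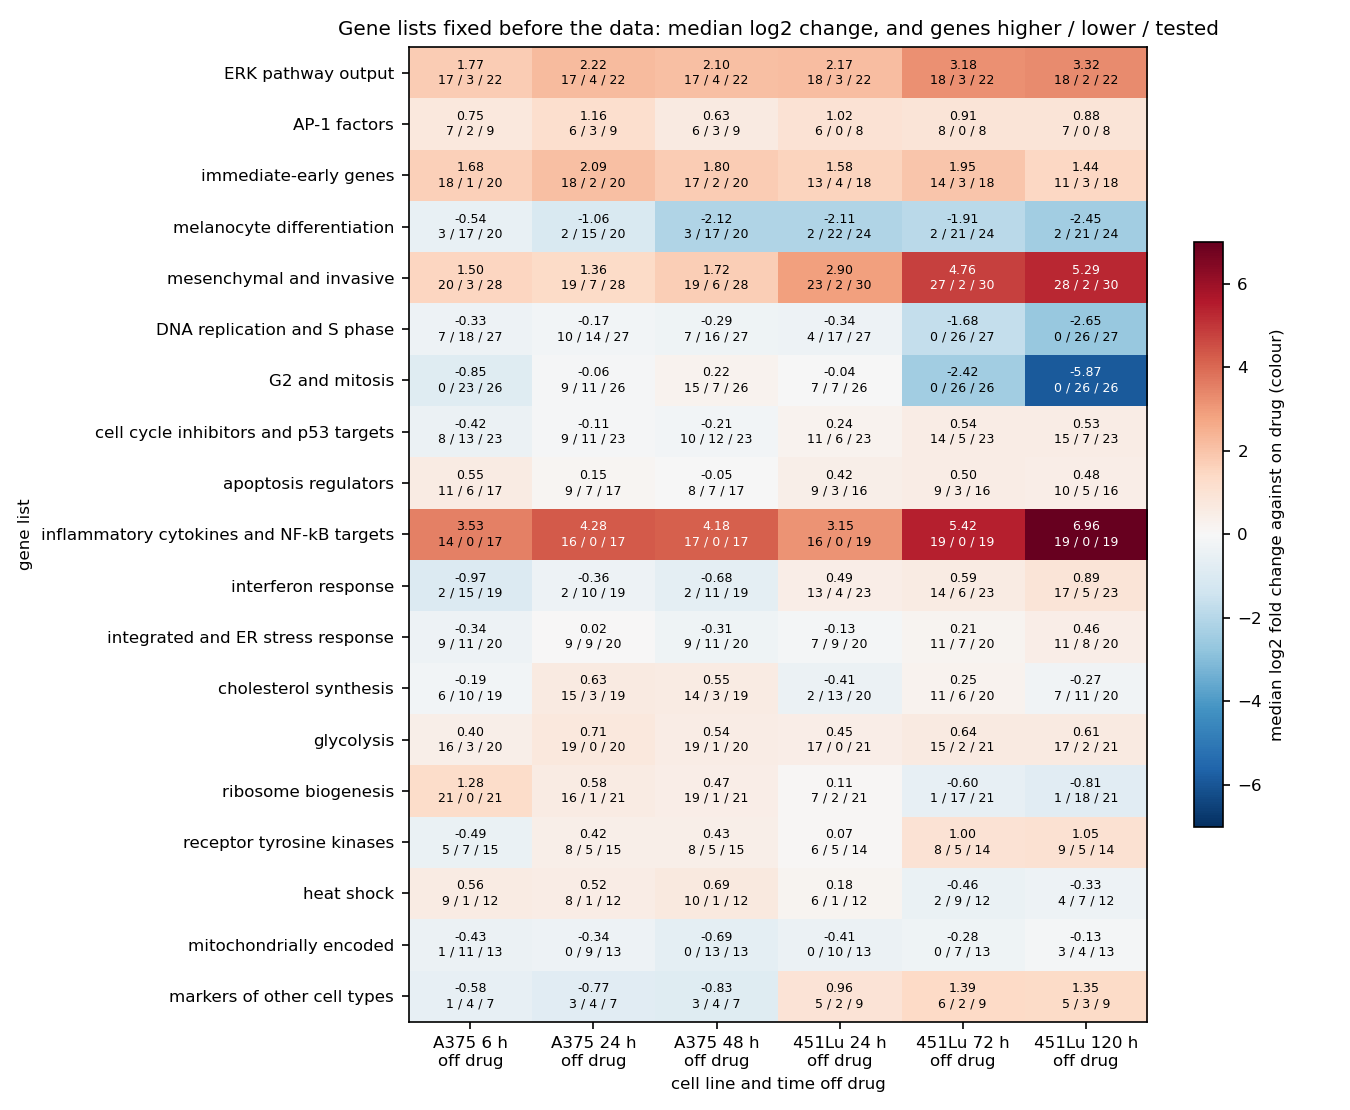
Median fitted log2 fold change against on drug (colour and upper number) of 19 gene lists (vertical axis) at 6 combinations of cell line and time (horizontal axis), with the number of genes higher, lower and tested in each list. The G2 and mitosis list went from -0.04 at 24 h to -5.87 at 120 h in 451Lu and stood at 0.22 at 48 h in A375.

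Successive times in A375 were compared to ask which changes came late. Between 6 and 24 h AREG rose a further 28.8-fold from 25.6 ± 3.26 CPM, PTGES, a prostaglandin synthase gene, 26.8-fold and ADAMTS4, a matrix protease gene, 27.6-fold, while THBS1 fell 44.2-fold from 83.7 ± 5.06 to 1.85 ± 0.317 CPM and NCOA5 fell 16.4-fold. HAS2, which makes hyaluronan, went from 3 counts to 4.86 ± 0.386 CPM, a ratio of 35.3 (counting interval 11.8 to 173). Of 26 G2 and mitosis genes 23 rose and 0 fell between 6 and 24 h, also adjusted over the list alone, with camera adjusted p = 3.92e-12 and adjusted p = 0.0227 with an estimated correlation. Ribosome biogenesis genes fell in 19 of 21 cases with 0 up, also adjusted over the list alone (camera adjusted p = 9.98e-12, adjusted p = 0.0261 with an estimated correlation), and cholesterol synthesis genes rose in 17 of 19 with 0 down, also adjusted over the list alone (camera adjusted p = 6.45e-11, adjusted p = 0.209 with an estimated correlation). In all 10080 genes changed, 5133 up and 4947 down, and 4081 passed the test against 1.5-fold. The balance turned with RLE size factors (4970 up, 5094 down) and with DESeq2 (4090 up, 4116 down).

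From 24 to 48 h in A375, MMP1, which encodes interstitial collagenase, rose 7.89-fold from 8.002 ± 1.39 to 64.2 ± 3.90 CPM, with adjusted p = 3.64e-22, SCUBE2 rose 7.01-fold and HAS2 5.80-fold. IL33, an alarmin cytokine gene, fell 9.71-fold, DCT 6.72-fold and MLANA 5.74-fold. Melanocyte genes fell in 18 of 20 cases and rose in 1, also adjusted over the list alone, with camera adjusted p = 2.15e-42 and adjusted p = 0.00664 with an estimated correlation. G2 and mitosis genes rose in 22 of 26 with 0 down (23 and 0 adjusted over the list alone), with camera adjusted p = 1.61e-09 and adjusted p = 0.0193 with an estimated correlation. In all 4318 genes changed, 2048 up and 2270 down, and the count was 215 in the test against 1.5-fold and 2221 with DESeq2.

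In 451Lu the first comparison asked how expression had changed 24 h after dabrafenib was withdrawn. SPP1, which encodes the secreted protein osteopontin, rose from 0.747 ± 0.0402 to 259 ± 46.6 CPM, a log2 fold change of 8.43 ± 0.24 with adjusted p = 8.29e-14, and MMP9, a gelatinase gene, from 0.360 ± 0.0396 to 109 ± 20.9 CPM. KCNN4 (ENSG00000104783), which encodes a calcium-activated potassium channel, was at least 113-fold higher and EDARADD at least 84.0-fold, from 0 counts on drug. The adjacent non-coding genes AC112721.2 and AC112721.1 were at least 63.6-fold and 56.9-fold higher. TRPM1, a melanocyte channel gene, fell 124-fold from 76.6 ± 1.41 CPM, GALNT3 186-fold, CFAP61 85.6-fold and PRDM7 52.9-fold. DUSP6 was 22.8-fold higher, SPRY4 3.99-fold, FOSL1 6.96-fold, JUNB 2.54-fold, CCND1 6.00-fold and AXL 22.9-fold, while MITF fell 4.10-fold from 587 ± 5.14 to 143 ± 9.23 CPM. MAPK3 fell, with a log2 fold change of -0.43 ± 0.09. It did not pass the test against 1.5-fold, and over the alternatives its adjusted p ran from 3.66e-07 to 1.

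Melanocyte genes fell in 22 of 24 cases at 24 h in 451Lu and rose in 2 (the same adjusted over the list alone), OCA2, a melanosome channel gene, by 21.3-fold and SLC45A2, a melanosome transporter gene, by 8.82-fold, with camera adjusted p = 3.17e-35 and adjusted p = 0.0605 with an estimated correlation. Of 30 mesenchymal and invasive genes 23 rose and 2 fell (24 and 2 adjusted over the list alone), NT5E by 29.3-fold, PLAUR, the urokinase receptor gene, by 35.4-fold and the matrix gene TNC by 18.7-fold, with camera adjusted p = 4.30e-29 and adjusted p = 0.0605 with an estimated correlation. ERK pathway output had 18 up and 3 down of 22, also adjusted over the list alone, HMGA2 by 11.8-fold and PHLDA1 by 8.93-fold, with camera adjusted p = 3.77e-32 and adjusted p = 0.0224 with an estimated correlation. Immediate-early genes had 13 up and 4 down of 18, also adjusted over the list alone (camera adjusted p = 1.23e-09, adjusted p = 0.0551 with an estimated correlation), and AP-1 factors 6 up and 0 down of 8, also adjusted over the list alone (camera adjusted p = 1.55e-04, adjusted p = 0.21 with an estimated correlation).

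The cytokine list had 16 up and 0 down of 19 at 24 h in 451Lu, also adjusted over the list alone, LIF by 216-fold to 554 ± 165 CPM, with camera adjusted p = 7.42e-08 and adjusted p = 0.24 with an estimated correlation. Its median log2 change was 3.15, or 2.80 with genes at the floor set to their bound. Interferon genes rose in 13 of 23 cases and fell in 4 (the same adjusted over the list alone), IFIT2 by 6.22-fold and OASL by 23.3-fold, both antiviral genes, with camera adjusted p = 2.43e-04 and adjusted p = 0.182 with an estimated correlation. Among cell cycle inhibitors CDKN1A (ENSG00000124762) rose 48.7-fold from 2.64 ± 0.376 to 128 ± 15.4 CPM and CDKN2B, which encodes the inhibitor p15, 11.6-fold. That list had 11 up and 6 down of 23 (11 and 7 adjusted over the list alone), with camera adjusted p = 0.00654 and adjusted p = 0.15 with an estimated correlation. Apoptosis regulators had 9 up and 3 down of 16, also adjusted over the list alone (camera adjusted p = 1.55e-04, adjusted p = 0.0837 with an estimated correlation), and PMAIP1, which encodes the BH3-only protein NOXA, rose 7.20-fold beside the survival gene BCL2A1 at 3.83-fold. Cholesterol synthesis genes fell in 13 of 20 cases and rose in 2 (14 and 3 adjusted over the list alone), DHCR7 by 2.80-fold and LSS by 2.59-fold, with camera adjusted p = 8.79e-04 and adjusted p = 0.0713 with an estimated correlation.

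At 24 h in 451Lu, 7 of 26 G2 and mitosis genes rose and 7 fell (the same adjusted over the list alone), UBE2C by 1.64-fold up and AURKB by 1.66-fold down, with camera adjusted p = 0.845. Neither UBE2C (adjusted p = 0.0732, over its alternatives 9.00e-23 to 0.0732) nor AURKB (adjusted p = 0.0807, over its alternatives 8.43e-17 to 0.0807) passed against 1.5-fold. DNA replication genes had 4 up, RRM2 by 2.47-fold, and 17 down of 27, also adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.558 with an estimated correlation). Ribosome biogenesis genes had 7 up and 2 down of 21, also adjusted over the list alone (camera adjusted p = 0.832), and glycolysis genes 17 up and 0 down of 21, also adjusted over the list alone, PKM by 2.36-fold (camera adjusted p = 1.79e-06, adjusted p = 0.15 with an estimated correlation). Integrated and ER stress genes had 7 up and 9 down of 20, also adjusted over the list alone, ASNS, which makes asparagine, by 3.66-fold lower (camera adjusted p = 0.167). Receptor tyrosine kinases had 6 up and 5 down of 14, also adjusted over the list alone, KIT by 5.48-fold lower and FGFR1 by 4.52-fold higher (camera adjusted p = 0.615). Mitochondrially encoded genes had 10 of 13 down and 0 up (11 and 0 adjusted over the list alone, camera adjusted p = 0.0398, adjusted p = 0.629 with an estimated correlation). Markers of other cell types had 5 up and 2 down of 9, also adjusted over the list alone, KRT18 by 3.33-fold higher and LUM by 5.23-fold lower, and camera gave the direction down (adjusted p = 0.845) where their median log2 change was 0.96. In all 7491 of 13851 genes changed, 4044 higher and 3447 lower, and 2373 passed the test against 1.5-fold.

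At 72 h against on drug in 451Lu, KCNN4 went from 0 counts to 112 ± 1.61 CPM, at least 1257-fold higher, with adjusted p = 4.92e-15. Also from 0 counts on drug, CCL2, a monocyte attractant, was at least 394-fold higher, PECAM1 (ENSG00000261371), an adhesion gene of endothelial cells and leukocytes, at least 250-fold and CCL7 at least 178-fold. PRDM7 fell 253-fold, GALNT3 250.5-fold and DCT 107-fold, and LINC01531 had 0 counts, at least 106-fold lower. Without 72 h replicate 1 the fitted log2 change was 9.99 for CCL7, against 10.70, and -8.63 for PRDM7, against -7.98. For DCT it was -7.67 without 72 h replicate 2, against -6.74. MLANA fell 65.0-fold and PMEL, which encodes the fibril protein of melanosomes, fell from 8798 ± 400.3 to 400.0 ± 79.3 CPM. DUSP6 was 52.1-fold higher, SPRY4 8.89-fold, CCND1 11.4-fold, AXL 72.8-fold and JUNB 4.66-fold, while FOSL1 was 2.42-fold higher and MITF 2.11-fold lower. MAPK3 had a log2 fold change of -0.02 ± 0.09 with adjusted p = 0.882.

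All 26 G2 and mitosis genes fell at 72 h in 451Lu, also adjusted over the list alone, with a median log2 change of -2.42, camera adjusted p = 4.89e-33 and adjusted p = 0.0679 with an estimated correlation. MKI67, the proliferation antigen, fell 7.24-fold from 431 ± 5.76 CPM, FOXM1, a factor that drives mitotic genes, 9.60-fold and BIRC5, which encodes survivin, 7.56-fold. DNA replication genes fell in 26 of 27 cases with 0 up, also adjusted over the list alone, MCM4 by 3.34-fold and TK1 by 4.89-fold, with camera adjusted p = 1.84e-19 and adjusted p = 0.0505 with an estimated correlation. CDKN1A rose 121-fold to 319 ± 21.0 CPM and CDKN2B 24.6-fold, in a list with 14 up and 5 down of 23 (15 and 5 adjusted over the list alone), with camera adjusted p = 0.00316 and adjusted p = 0.111 with an estimated correlation. Ribosome biogenesis genes had 1 up and 17 down of 21, also adjusted over the list alone, NPM1 by 1.82-fold (camera adjusted p = 4.68e-04, adjusted p = 0.191 with an estimated correlation). Heat shock genes had 2 up and 9 down of 12, also adjusted over the list alone, HSP90AA1 by 1.87-fold (camera adjusted p = 0.0302, adjusted p = 0.286 with an estimated correlation).

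Mesenchymal and invasive genes rose in 27 of 30 cases at 72 h in 451Lu and fell in 2, also adjusted over the list alone, NT5E by 96.6-fold to 1235 ± 46.1 CPM, with camera adjusted p = 2.40e-31 and adjusted p = 0.0505 with an estimated correlation. Their median log2 change was 4.76, or 4.82 with genes at the floor set to their bound. All 19 cytokine genes rose, also adjusted over the list alone, LIF to 2701 ± 613 CPM, with a median log2 change of 5.42 (4.46 with genes at the floor set to their bound), camera adjusted p = 1.74e-13 and adjusted p = 0.133 with an estimated correlation. ERK pathway output had 18 up and 3 down of 22, also adjusted over the list alone (camera adjusted p = 4.88e-36, adjusted p = 0.00905 with an estimated correlation). Immediate-early genes had 14 up and 3 down of 18, also adjusted over the list alone (camera adjusted p = 5.2e-10, adjusted p = 0.0424 with an estimated correlation). Melanocyte genes had 2 up and 21 down of 24, also adjusted over the list alone (camera adjusted p = 2.14e-21, adjusted p = 0.0679 with an estimated correlation). Receptor tyrosine kinases had PDGFRB at 95.4-fold higher and KIT at 12.9-fold lower, with 8 up and 5 down of 14 (the same adjusted over the list alone, camera adjusted p = 0.253). Integrated and ER stress genes had 11 up and 7 down of 20, also adjusted over the list alone, and camera gave the direction down (adjusted p = 0.489) where the median log2 change was 0.21. Markers of other cell types had 6 up and 2 down of 9, also adjusted over the list alone (camera adjusted p = 0.589), with LUM 13.3-fold lower beside the rise of PECAM1. In all 9371 genes changed, 4742 higher and 4629 lower, and 4387 passed the test against 1.5-fold. Unfiltered, 4587 were higher and 5025 lower.

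By 120 h in 451Lu the proliferation genes had fallen further. MKI67 (ENSG00000148773, chromosome 10, 128096659 to 128126385) went from 431 ± 5.76 CPM on drug to 3.51 ± 0.196, a log2 fold change of -6.94 ± 0.11 with adjusted p = 3.47e-17, BIRC5 fell 92.5-fold and TPX2, a spindle assembly gene, 28.2-fold. All 26 G2 and mitosis genes fell, also adjusted over the list alone, with a median log2 change of -5.87, camera adjusted p = 6.69e-54 and adjusted p = 0.0577 with an estimated correlation. In the DNA replication list 26 of 27 fell and 0 rose, also adjusted over the list alone, TK1 by 21.5-fold, with camera adjusted p = 9.95e-34 and adjusted p = 0.0577 with an estimated correlation. CDKN1A reached 555 ± 68.2 CPM, 211-fold above on drug, and its list had 15 up and 7 down of 23, also adjusted over the list alone (camera adjusted p = 0.0129, adjusted p = 0.159 with an estimated correlation). Ribosome biogenesis genes had 1 up and 18 down of 21, also adjusted over the list alone, NCL, the nucleolin gene, by 2.55-fold (camera adjusted p = 3.87e-05, adjusted p = 0.134 with an estimated correlation).

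At 120 h in 451Lu, IL1B (ENSG00000125538), which encodes interleukin 1 beta, rose from 0.692 ± 0.118 to 2319 ± 872 CPM, a log2 fold change of 11.70 ± 0.57 with adjusted p = 1.47e-11, and LIF reached 5801 ± 936 CPM. From 0 counts on drug KCNN4 was at least 2031-fold higher, PECAM1 at least 1239-fold, PDGFB, a growth factor gene, at least 652-fold, TNFSF10, which encodes the death ligand TRAIL, at least 483-fold and CCL2 at least 447-fold. All 19 cytokine genes rose, also adjusted over the list alone, with a median log2 change of 6.96 (6.24 with genes at the floor set to their bound), camera adjusted p = 9.15e-16 and adjusted p = 0.134 with an estimated correlation. Mesenchymal and invasive genes rose in 28 of 30 cases and fell in 2, also adjusted over the list alone, with NT5E at 138-fold and AXL at 141-fold, a median log2 change of 5.29 (5.24 with genes at the floor set to their bound), camera adjusted p = 6.09e-27 and adjusted p = 0.0577 with an estimated correlation. TRPM1 had 0 counts, at least 598-fold lower, MLANA fell 145-fold and DCT 583-fold, while MITF was 2.103-fold lower. Melanocyte genes had 2 up and 21 down of 24, also adjusted over the list alone (camera adjusted p = 7.72e-18, adjusted p = 0.127 with an estimated correlation).

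DUSP6 was 55.0-fold higher at 120 h in 451Lu, SPRY4 11.3-fold, CCND1 11.8-fold, JUNB 5.21-fold and FOSL1 2.02-fold. ERK pathway output had 18 up and 2 down of 22, also adjusted over the list alone, IER3 by 88.7-fold, with camera adjusted p = 4.25e-28 and adjusted p = 0.0109 with an estimated correlation. MAPK3 fell, with a log2 fold change of -0.46 ± 0.09. It did not pass against 1.5-fold, with adjusted p over its alternatives from 2.14e-08 to 1. Interferon genes had 17 up and 5 down of 23, also adjusted over the list alone, IRF1 by 7.62-fold (camera adjusted p = 0.129). Cholesterol synthesis genes had 7 up, SQLE by 3.41-fold, and 11 down, LSS by 3.06-fold, of 20 (the same adjusted over the list alone, camera adjusted p = 0.828). Mitochondrially encoded genes had 3 up and 4 down of 13, also adjusted over the list alone (camera adjusted p = 0.649). Markers of other cell types had 5 up and 3 down of 9, also adjusted over the list alone, LUM by 24.3-fold lower (camera adjusted p = 0.435). In all 10224 genes changed, 5161 higher and 5063 lower, and 5688 passed the test against 1.5-fold. Unfiltered, 5284 were higher and 5459 lower.

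**Figure D3:**
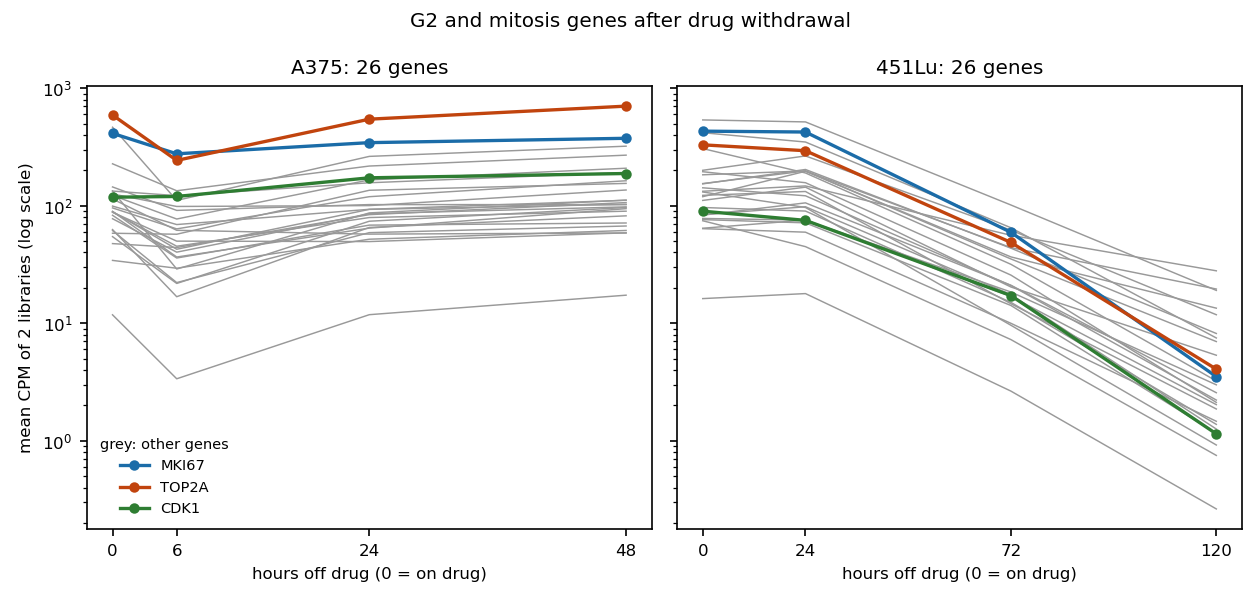
Mean CPM of 2 libraries on a log scale (vertical axis) against hours off drug (horizontal axis) for the 26 G2 and mitosis genes in each line, 1 line per gene. In 451Lu, MKI67 went from 431 CPM on drug to 59.4 at 72 h and 3.51 at 120 h, and in A375 from 412.6 on drug to 374.6 at 48 h.

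Successive times in 451Lu were compared to ask which changes came late. Between 24 and 72 h IL1B rose 66.8-fold to 325 ± 213 CPM, with adjusted p = 2.43e-08, ITGA11, a collagen-binding integrin gene, 60.8-fold and UNC13A 41.8-fold, while MLANA fell 13.5-fold and KIF20A 9.94-fold. The IL1B libraries at 72 h had 475 and 174 CPM, and its log2 fold change of 6.06 was 5.16 without 72 h replicate 1. All 26 G2 and mitosis genes and all 27 DNA replication genes fell, also adjusted over the list alone, with camera adjusted p = 5.50e-94 and 2.59e-35, and adjusted p = 0.0193 for each with an estimated correlation. Cholesterol synthesis genes rose in 16 of 20 cases with 0 down (17 and 0 adjusted over the list alone), with camera adjusted p = 4.57e-12 and adjusted p = 0.0141 with an estimated correlation. ERK pathway output had 20 up and 0 down of 22 (20 and 1 adjusted over the list alone), with camera adjusted p = 9.38e-16 and adjusted p = 0.0141 with an estimated correlation. In all 7126 genes changed, 3589 up and 3537 down, and 1768 passed the test against 1.5-fold. Unfiltered, 3346 were up and 3739 down.

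From 72 to 120 h in 451Lu the complement gene C3 rose 12.4-fold from 22.7 ± 9.92 to 279 ± 110 CPM, with adjusted p = 2.24e-08, FGF2, a growth factor gene, 9.23-fold, TFPI2 9.46-fold and IL1B 7.16-fold. Without 72 h replicate 1 the log2 fold change of IL1B was 3.73, against 2.84, and that of TFPI2 3.92, against 3.24, which was 2.65 without 120 h replicate 1. NCAPG, a condensin gene, fell 21.6-fold, ASPM, a spindle pole gene, 18.1-fold and E2F2 17.1-fold. ASPM had a log2 fold change of -4.175, and of -4.805 without 120 h replicate 2. TRPM1 went from 23 counts to 0 (adjusted p = 0.00562), at least 9.04-fold lower, a call lost without 72 h replicate 2, where adjusted p was 0.272 in a range of 5.73e-08 to 0.272 over 11 alternatives. G2 and mitosis genes fell in 26 of 26 cases, also adjusted over the list alone, with adjusted p = 0.0372 with an estimated correlation. Cholesterol synthesis genes fell in 13 of 20 with 0 up (15 and 0 adjusted over the list alone), with camera adjusted p = 4.44e-06 and adjusted p = 0.0372 with an estimated correlation. Camera called ERK pathway output up (adjusted p = 0.0364; adjusted p = 0.288 with an estimated correlation), with 8 up and 4 down of 22 (9 and 4 adjusted over the list alone), where its mean log2 change was -0.01 and its median 0.10. In all 4531 genes changed, 2297 up and 2234 down, and the count was 550 in the test against 1.5-fold, 2975 with DESeq2 (1442 up, 1533 down) and 2851 without 72 h replicate 2.

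The last comparison asked where the 24 h change differed between the lines, which also came off different drugs. AREG rose in A375 and had a log2 change of -0.25 ± 1.05 in 451Lu (4 counts at 24 h and 6 on drug), a difference (A375 minus 451Lu) of 12.13 ± 1.64 with adjusted p = 7.57e-07. With 1 of the 4 libraries of 451Lu left out, that difference ran from 10.59 (without on-drug replicate 1) to 13.14 (without 24 h replicate 2). SPP1 rose in 451Lu and fell with a log2 change of -0.36 ± 0.14 in A375, a difference of -8.76 ± 0.28 with adjusted p = 8.87e-19. COL15A1, a basement membrane collagen gene, fell in A375 and rose in 451Lu, a difference of -6.55 ± 0.56. DUSP6 differed by -2.24 ± 0.12, JUNB by 1.86 ± 0.16, CCND1 by 0.77 ± 0.08, MAPK3 by 0.61 ± 0.11 and SPRY4 by 0.35 ± 0.08, each past the threshold. Against 1.5-fold, SPRY4 (adjusted p = 1, over its alternatives 9.88e-04 to 1) and MAPK3 (adjusted p = 0.52, over its alternatives 1.19e-06 to 0.52) did not pass. FOSL1 differed by 0.38 ± 0.13 (adjusted p = 0.02) and MITF by 0.29 ± 0.09 (adjusted p = 0.00617), but the FOSL1 call ended in 4 of 14 alternatives (adjusted p 0.00462 to 1) and the MITF call in 3 of 14 (0.00325 to 1). The FOSL1 differences were 0.29 without A375 on-drug replicate 1, 0.27 without A375 24 h replicate 1 and 0.27 without 451Lu 24 h replicate 2, and the MITF differences 0.22 without A375 24 h replicate 2 and 0.21 without 451Lu 24 h replicate 1. AXL differed by 1.40 ± 0.93 (adjusted p = 0.225), not past the threshold, and by 2.89 without A375 on-drug replicate 2 (adjusted p = 0.039, in a range of 0.039 to 0.661) and 0.59 without replicate 1.

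Cholesterol synthesis genes differed between the lines at 24 h: 18 of 20 changed more in the upward direction in A375 and 0 in 451Lu (19 and 0 adjusted over the list alone), with a median difference of 1.26, camera adjusted p = 7.81e-21 and adjusted p = 0.0078 with an estimated correlation. This list also moved with time within a line. Its median log2 change was -0.19, 0.63 and 0.55 at 6, 24 and 48 h in A375. In 451Lu it was -0.41, 0.25 and -0.27 at 24, 72 and 120 h. A difference in timing therefore cannot be told apart from one in size. Of 20 immediate-early genes 11 differed upward and 4 downward, also adjusted over the list alone, with a median difference of 0.77, camera adjusted p = 1.04e-07 and adjusted p = 0.0175 with an estimated correlation. Mesenchymal and invasive genes had 4 upward and 14 downward of 30, also adjusted over the list alone (camera adjusted p = 2.68e-05, adjusted p = 0.319 with an estimated correlation), and melanocyte genes 14 upward and 2 downward of 24, also adjusted over the list alone (camera adjusted p = 6.88e-05, adjusted p = 0.382 with an estimated correlation). Interferon genes had 5 upward and 10 downward of 25, also adjusted over the list alone (camera adjusted p = 0.00905, adjusted p = 0.0837 with an estimated correlation). In all 7642 of 15481 genes differed, 4240 upward and 3402 downward, and 2722 passed against 1.5-fold.

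Shared changes at 24 h were counted over the 12814 genes tested in both lines. FOSL1, CCND1, DUSP6 and NT5E were among 2382 genes higher in both lines, where 1452 were expected from the counts in each (Fisher's exact test, one-sided, p = 1.57e-295). MITF and GALNT3 were among 1783 genes lower in both, where 1161 were expected (Fisher's exact test, one-sided, p = 3.60e-149). Together 4165 genes changed the same way, against 2613 expected, and 1400 changed in opposite directions, against 2602 expected. Using the test against 1.5-fold, 945 genes changed the same way, against 291 expected. Genes are not independent replicates, so these p-values do not count independent events.

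**Figure D4:**
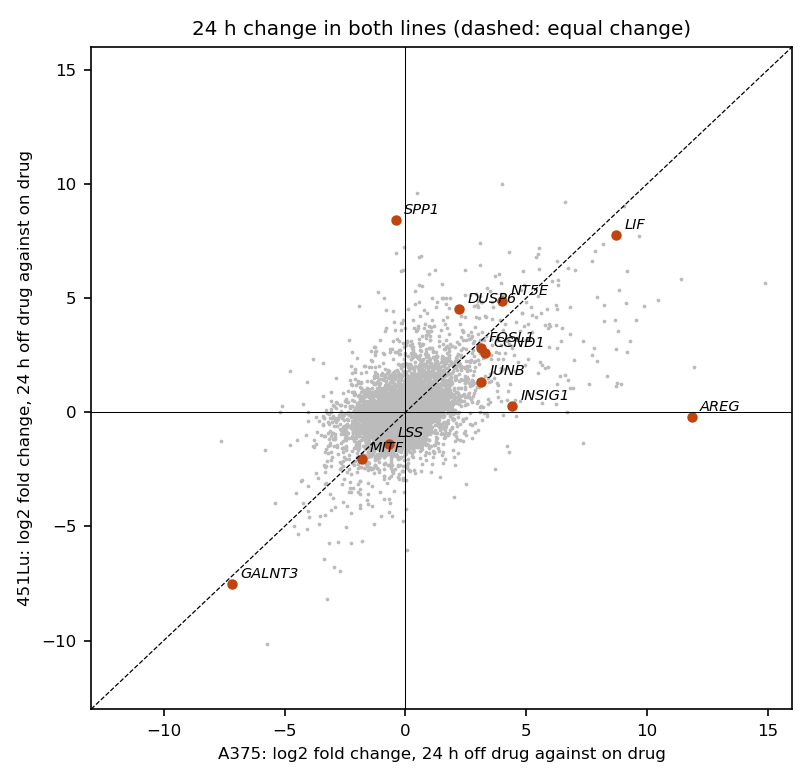
Fitted log2 fold change at 24 h off drug against on drug in 451Lu (vertical axis) against that in A375 (horizontal axis). There is 1 point per gene tested in both lines and in the joint fit, with a dashed line for equal change and 12 genes named. Plotted values come from the fit of each line. In the joint fit, which can differ slightly, AREG changed by 11.88 in A375 and -0.25 in 451Lu. There SPP1 changed by -0.36 and 8.398, and MITF by -1.77 and -2.06.

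Across all comparisons, the signs of the median, the mean and the camera test of a list differed in 23 of 209 list tests, of which 1, ERK pathway output from 72 to 120 h in 451Lu, was past the threshold. Camera called 116 of the 209 list tests, of which 31 held with an estimated correlation.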

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

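The tests of reads of the BRAF pseudogene, of the FN1 share of counts, of the longer time off drug, of a single library out of line, of marker levels against that of PECAM1 and of CDH5 counted as raised were chosen only after the result was seen. The change at 24 h differed between A375 and 451Lu, in a test of the difference itself, for 7642 of 15481 genes. The genes from AREG to MAPK3 and the 2 lists after them were past the threshold for that difference. DUSP6, SPRY4, FOSL1, JUNB, MITF, CCND1 and MAPK3 are given because they were always named. SPRY4, FOSL1 and MITF differed by less than the median absolute log2 difference over all genes, 0.533. The lines also came off different drugs, so line and drug cannot be separated. Because 24 h was the only time off drug that the lines shared, a difference in timing cannot be told apart either. BRAF and NDUFB2 stand out by their level on drug, and the G2 and mitosis list and the genes beside PECAM1 by their changes at 72 and 120 h. For the G2 and mitosis list the difference at 24 h was not past the threshold (camera adjusted p = 0.848).

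On the log2 scale, A375 minus 451Lu, AREG differed by 12.13 (10.59 to 13.14 with 1 library left out), COL15A1 by -6.55 and SPP1 by -8.76. With 0 counts in A375 on drug set to the floor, ARC differed by at least 6.737, IL11 by at least 5.942 and PTPN22 by at least 5.459. PTPRN, with 1 count in 451Lu at 24 h and 2 on drug, differed by 7.418 with both groups set to the floor. Toward 451Lu, with 0 counts set to the floor in 451Lu on drug for PDGFC and EDARADD and in A375 at 24 h for KCNJ2, the differences were at least as far below 0 as -4.107 for PDGFC, -4.237 for KCNJ2 and -5.856 for EDARADD. DUSP6 differed by -2.235, SPRY4 by 0.3463, FOSL1 by 0.3836, JUNB by 1.862, MITF by 0.2896, CCND1 by 0.7681 and MAPK3 by 0.6131. Of 14 alternatives each, the FOSL1 call ended in 4 (adjusted p 0.00462 to 1), the MITF call in 3 (adjusted p 0.00325 to 1), and the SPRY4 and MAPK3 calls in the test against 1.5-fold (adjusted p = 1 and adjusted p = 0.52). The median difference was 0.7704 for immediate-early genes and 1.26 for cholesterol synthesis genes.

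BRAF and NDUFB2 had far more counts in A375 than in 451Lu on drug: 4406 ± 68.0 against 72.5 ± 0.298 CPM for BRAF and 7165 ± 129 against 122.6 ± 5.44 CPM for NDUFB2 (SD, n = 2). A gain of the segment in A375 fits: its 26 tested neighbours within 1 Mb had a median log2 ratio of 3.828, where 99.8% of 14855 runs of as many neighbouring genes lay lower and 29 reached it or more. Within it, 22 neighbours were higher in A375 and 2 lower, HIPK2 (-1.86) and PARP12 (-0.85). Some of the higher ones were near 0 in 451Lu, such as RP11-744I24.3 (0 CPM) and TMEM178B (0.029 CPM), where the size of a ratio is uncertain. Others were well counted in both lines, such as MRPS33 (3720 against 58.6 CPM) and AGK (511 against 70.4 CPM). Some neighbours overlap, such as ADCK2 and NDUFB2-AS1, and may share reads, so the neighbours are not all separate evidence. Reads shared with the BRAF pseudogene would be counted for BRAF, so the 22 higher neighbours argue against them as the cause along the segment. For BRAF itself such reads stay open: the pseudogene had 76 counts beside 148613 for BRAF in A375 on drug, a ratio of 0.0005114, but shared reads may all have been counted for BRAF. BRAF starts at 140719327, before the end of NDUFB2 at 140722790, so reads may be shared between these 2 genes, a ratio cannot say which line moved, DNA was not measured here, and the parental A375 and 451Lu lines were not analysed here.

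The G2 and mitosis genes fell in 451Lu by 72 and 120 h (26 of 26 each, adjusted p = 0.0679 and adjusted p = 0.0577 with an estimated correlation). The share of counts taken by FN1, at most 6.25%, is too small to account for the fall. With FN1 taken out and libraries scaled by their remaining totals alone, the median log2 change of the list at 120 h was -6.061. It ran from -6.229 to -5.673 over pairs of libraries, against -6.152 with FN1 kept and totals alone. The small size of this shift was fixed in advance by the FN1 share. Depth differed too little to account for the fall at 120 h: totals were 13755264 and 12084012 counts there, against 14097739 and 16447548 on drug. With all libraries thinned to 9714190 counts the median of the list was -5.642, against -5.875 in full, and 26 of 26 genes were still lower. Because changes are scaled by depth, thinning was bound to shift the median little, so it cannot by itself exclude low depth. The thinned change at 72 h was not computed. A longer time off drug and a difference between the lines cannot be told apart: in A375 the list fell at 6 h (23 of 26, median -0.85, adjusted p = 0.0180 with an estimated correlation) and stood at 0.2236 at 48 h, and no later time was analysed here. The difference of line and drug was not tested at 72 or 120 h. No on-drug libraries were matched to those times, so time in culture cannot be told apart from withdrawal either.

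PECAM1, CCL2, CCL7, SPP1 and IL1B, genes better known from leukocytes, macrophages or endothelium, rose in 451Lu off drug. Of 9 abundant markers of such cells, with CDH5 not analysed here, 2 were above 1 CPM at 120 h with a rise of over 2 on the log2 scale, FCER1G from 0.715 to 6.36 CPM and LAPTM5 from 0 to 1.79 CPM. CD34 stood 2.39 higher on that scale, at 0.470 CPM, and CD68 1.52 higher, at 0.598 CPM, while PTPRC had 0 counts at every time and VWF went from 0.923 to 0.342 CPM. Such cells mixed into the cultures are argued against, since no marker reached more than 0.0575 of the PECAM1 level of 110.7 CPM and, even with CDH5 counted as raised, 6 of the 10 did not stand over 2 higher. For 5 of 5 genes all 4 libraries of 72 and 120 h lay above both on-drug libraries. Genes taken as largest rises had to show such a separation between 2 groups, so this outcome was partly fixed by their choice. It therefore cannot exclude a single library out of line, and a change of the melanoma cells themselves was not tested.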

How the results depend on the processing

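Of 488 named results, 28 calls ended in the test against 1.5-fold, and of 2024 values with 1 library left out 9 were weaker and 1 stronger. No call reversed in direction in the alternatives run, of which the fit of all 16 libraries covered 470 named results and the fits of 2 groups 468, and 1 uncalled result changed sign. Which direction held more genes turned in some, among them these. With RLE size factors A375 had 5318 higher and 5198 lower at 6 h and 5405 and 5113 at 24 h, and DESeq2 gave 4748 and 3853, then 4670 and 3763. Without the low-count filter the numbers were 5154 and 5567 for A375 at 48 h and 4587 and 5025, then 5284 and 5459, for 451Lu at 72 and 120 h. In the test against a 1.5-fold change the counts were lower by construction, since it asks for a larger change: 4566, 4257 and 4525 genes for A375 at 6, 24 and 48 h, and 2373, 4387 and 5688 for 451Lu at 24, 72 and 120 h. For successive times they were 4081 and 215 in A375 and 1768 and 550 in 451Lu. The line difference held 2722 genes and the overlap 945. DESeq2 gave 2221 genes (848 higher, 1373 lower) for A375 at 48 h against 24 h and 2975 (1442 and 1533) for 451Lu at 120 h against 72 h, and the cause was not tested. With 1 library left out, the lone sample of its group is assumed to vary like the other groups. The ranges were then 9531 to 9892, 9413 to 9966 and 9665 to 10045 for A375 at 6, 24 and 48 h. In 451Lu they were 5978 to 6587, 8288 to 8517 and 9369 to 9880 at 24, 72 and 120 h. Successive times gave 9037 to 9517 and 2983 to 3983 in A375, and 5837 to 6200 and 2851 to 4052 in 451Lu, the lowest without replicate 2 of 451Lu at 72 h; the cause was not tested. The line difference ran from 6712 to 7153 and the overlap from 3443 to 3983. With the replicate block the counts were 10473, 10340 and 10373 in A375, 7840, 9632 and 10435 in 451Lu, 9955 and 4035 for successive times in A375, 7453 and 5041 in 451Lu, 7696 for the line difference and 4290 for the overlap. The melanocyte list from 72 to 120 h in 451Lu lost its call with the replicate block (adjusted p = 0.05572, and adjusted p = 0.5772 with an estimated correlation). Of 116 list calls, 115 held with the replicate block, 113 with fry and 31 with an estimated correlation. Fry asks whether the genes of a list changed at all, not whether they changed more than other genes. It also called 53 list tests that camera did not, so the 113 are no support for a change beyond that of other genes. Depth limits a gene with 0 counts in a group to a bound, such as IL11 in A375 at 6 h. AXL in A375 on drug had 0.118 and 0.617 CPM in its 2 libraries, and with 1 of them left out its 6 h change was 2.105 or 4.40.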

Other observations

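The genes in this part were chosen after their values were seen. HBEGF, which encodes a ligand of the EGF receptor, rose in A375 from 9.64 ± 0.0389 to 50.4 ± 6.63 CPM at 6 h (adjusted p = 2.30e-21) and in 451Lu from 8.44 ± 0.333 to 118 ± 16.9 CPM at 120 h (adjusted p = 2.41e-14; SD, n = 2). TGFA was at 54.3 ± 2.53 CPM in A375 on drug and 55.0 ± 0.760 at 6 h (adjusted p = 0.817), and rose to 98.9 ± 2.01 CPM by 24 h and 132 ± 0.448 by 48 h. AREG in 451Lu reached 2.91 ± 1.67 CPM at 120 h (adjusted p = 2.04e-05), with 4.095 CPM in replicate 1 and 1.733 CPM in replicate 2, where A375 had 1087 ± 23.6 CPM at 48 h. EREG in 451Lu reached 17.4 ± 7.61 CPM at 120 h (adjusted p = 7.28e-09).

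MMP1, which encodes interstitial collagenase, rose in 451Lu from 17.7 ± 1.32 to 2829 ± 897 CPM at 72 h and 3340 ± 819 at 120 h (adjusted p = 8.10e-14). MMP3, which encodes stromelysin 1, rose in 451Lu from 1.54 ± 0.0825 to 87.0 ± 33.2 CPM at 120 h (adjusted p = 4.77e-10). In A375, MMP3 rose from 0.290 ± 0.0757 CPM on drug to 15.01 ± 0.0373 at 6 h (adjusted p = 3.61e-20) and was 1.59 ± 0.425 at 48 h, still above on drug (adjusted p = 1.51e-05). SRGN, which encodes the proteoglycan serglycin, rose in 451Lu from 0.267 ± 0.0126 to 339.8 ± 27.1 CPM at 120 h (adjusted p = 2.47e-17) and fell in A375 from 1.49 ± 0.559 to 0.412 ± 0.200 CPM at 48 h (0.553 in replicate 1 and 0.270 in replicate 2, adjusted p = 7.15e-04). FN1 was 135 ± 8.83 CPM in A375 on drug and 182 ± 9.06 at 48 h (adjusted p = 2.00e-08).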
